A study of Homo sapiens with 4 samples.

How the data were processed

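Total RNA of MCF10A cells was turned into stranded, ribosomal-RNA-depleted Illumina libraries and read as short paired ends, per the labels' protocols. The molecule field of the same labels says polyA RNA, so the selection step is described in more than one way. The 4 libraries analysed here were 2 controls at 0 h and 2 libraries after 1.5 h of TGF-β1 at 5 ng/ml. Their groups and replicate numbers were taken from the sample titles. The labels call them biological duplicates, and do not say that a replicate number marks a shared day or batch.

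The authors quantified each library with kallisto on GRCh38, per the submitters' processing notes. The kallisto version and the release of the transcript set are not given in the sources used here. The deposited tables hold 1 row per transcript with estimated counts, which share a read among the transcripts it could come from, per the file headers. The same deposited tables hold TPM values, which correct the estimated counts for transcript length, and effective transcript lengths in bases. The totals of estimated counts per library ran from 35737659 to 40792300. Mean levels are given with the SD between libraries, and some log2 fold changes with a standard error (SE). The shares of ribosomal protein mRNAs have 95% Wilson intervals from rounded counts, which cover counting error only.

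Of 173259 transcripts in the tables, 159239 (91.91%) matched a transcript of GENCODE release 29 on GRCh38 by identifier without version, and these belong to 34500 genes. The unmatched transcripts held 2.24% to 2.38% of the estimated counts of a library and entered no gene-level test. Estimated counts were summed per gene and rounded to whole numbers. Gene positions are those of GENCODE release 29 on GRCh38, counted from 1. Reads of near-identical genes are shared by the estimation, so SIK1 and SIK1B, and H4C15 and the other copies of the histone H4 gene, are uncertain as single genes.

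CPM values (counts scaled to library size) were computed with edgeR 4.0.16 in R 4.3.3, with TMM scaling and the genes kept by filterByExpr, 14774 in all. Groups were compared with edgeR's quasi-likelihood test without covariates, with Benjamini-Hochberg adjustment over these genes and a threshold of 0.05. This was fixed as the main test before the data were examined. The standard errors given with edgeR's log2 fold changes are the fold change divided by the square root of its F statistic, an approximation. DESeq2 1.42.0 (Wald test, 23178 genes with counts, 19649 with an adjusted p) was fixed as an alternative. The other alternatives fixed then were RLE scaling, no filter, a filter of at least 50 counts in 2 libraries, transcript lengths as an offset, the replicate number as a block, each library left out, single transcripts, limma 3.58.1 on log2(TPM + 1) and a threshold of 0.01. A robust and a version 4 quasi-likelihood fit, DESeq2 with the replicate block, DESeq2 without each library and DESeq2 on single transcripts were added after the data were seen.

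There were 29 gene lists, fixed before the data were examined and tested with limma's camera on log2 CPM (prior count 3, preset correlation 0.01, lists with at least 5 tested genes, adjusted over the lists). The same lists were tested with an estimated correlation and with fry. A list that passes only with the preset is not thereby shown to owe its call to correlated genes. Some genes stand in more than 1 list, so the list tests are not independent. The rule for genes named in the text was also fixed then. It took up to 12 higher and 8 lower called genes with the largest log2 fold change, a group mean of at least 50 counts and both treated libraries on 1 side of both controls. It added up to 3 genes with the smallest p from each list with a called gene. Among others it always took SMAD7, SKIL, ID1, SNAI1, PMEPA1, JUNB, MYC and PHF8. Since edgeR called no gene, the first parts of the rule gave 0 genes on its calls and were applied to DESeq2's calls, a choice made after the data were seen. The rule then named 50 genes. The results of 1 named gene and 1 gene list are not reported here.

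Both tests were tried on counts simulated for this comparison over 14774 genes, 200 of them changed. The simulation with independent libraries also raised 14 feedback regulators of TGF-β signalling 2-fold, which the percentages leave out. With libraries drawn independently, edgeR called 18% of the genes changed 2-fold, 88% of those changed 4-fold and 100% of those changed 8-fold or 16-fold. DESeq2 called 60%, 98%, 100% and 100% of them. Of its 280 calls, 89 were of unchanged genes, against 13 of edgeR's 171. When none was changed, DESeq2 called 29 genes and edgeR 0. With simulated libraries that kept the measured differences between replicate numbers, edgeR called 2%, 62%, 88% and 92% and DESeq2 64%, 98%, 100% and 100%. There, 1 of DESeq2's 182 calls was of an unchanged gene, and DESeq2 called 1 gene and edgeR 0 when none was changed. On the same simulated counts, edgeR with the replicate number as a block called 100% of the changed genes of each size, 30 of its 230 calls were of unchanged genes, and it called 9 genes when none was changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.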

Results

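MCF10A is an immortalised, non-tumorigenic line of human mammary epithelial cells. The cells analysed here stably carried a scramble shRNA, a hairpin meant to have no target. TGF-β1, a cytokine that signals through receptor kinases to SMAD2 and SMAD3, was added to the medium at 5 ng/ml. RNA was sequenced from 2 libraries at 0 h (control) and from 2 libraries after 1.5 h. The estimated counts came to 40792300 and 36693330 in control replicates 1 and 2, and to 40461473 and 35737659 in TGF-β1 replicates 1 and 2. In both groups the libraries numbered 2 stood apart from those numbered 1. Ribosomal protein mRNAs took 7.27% of gene counts in control replicate 1 and 7.24% in TGF-β1 replicate 1, against 9.27% and 9.52% in the replicates numbered 2. The 95% Wilson intervals, which cover counting error only, ran from 7.26% to 7.28%, 7.23% to 7.24%, 9.26% to 9.28% and 9.51% to 9.53%. The mRNA of PHF8, a histone demethylase that the labels' protocol mentions, was at 20.2 CPM (counts scaled to library size) in control replicate 1 and 20.0 CPM in TGF-β1 replicate 1, and at 3.88 and 3.998 CPM in the replicates numbered 2.

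The comparison of 1.5 h with 0 h asks which transcripts respond early to TGF-β1. SMAD7, the inhibitory SMAD that blocks the TGF-β receptor, rose 13.6-fold, from 8.43 ± 0.219 to 114 ± 20.3 CPM (mean ± SD, n = 2 libraries per group here and throughout). SNAI1, a zinc-finger repressor that drives epithelial-mesenchymal transition (EMT), rose 29.3-fold, from 0.312 ± 0.0932 to 9.26 ± 3.22 CPM. JUNB, a subunit of the AP-1 transcription factor, rose 7.70-fold, from 99.7 ± 33.3 to 768 ± 52.4 CPM. PLK2, a polo-like kinase and p53 target, fell from 84.4 ± 3.59 to 26.3 ± 7.52 CPM, 3.21-fold. "Rose" and "fell" are used of genes past the threshold of DESeq2's Wald test, a Benjamini-Hochberg adjusted p under 0.05. Statements that a gene did not pass in the comparison with TGF-β1 refer to fits without the replicate number as a block. With that block, edgeR called 49 of the 50 named genes, in a fit that also called unchanged genes in simulation. Each fit without 1 library sets a single library against libraries of both replicate numbers. Calls gained or lost in such a fit, here and below, therefore also carry the difference between replicate numbers.

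DESeq2 called 90 genes, 83 higher and 7 lower, and 82 of them changed at least 2-fold (77 higher, 5 lower). The main test, edgeR's quasi-likelihood test, called 0 of 14774 genes. Its smallest adjusted p was 0.0888, shared by SMAD7, by CSRNP1, a nuclear protein induced by AXIN1, and by BMF, a pro-apoptotic BH3-only protein. At an unadjusted p under 0.05 edgeR had 255 genes, 198 higher and 57 lower. With no changed gene, 739 would have such a p if libraries varied independently, and 14 did in simulated libraries that kept the measured differences between replicate numbers. All 90 genes called by DESeq2 were among the 255, and each moved the same way within replicates 1 and within replicates 2. In all 90, both TGF-β1 libraries lay on the same side of both controls, as they did in 16.2% of all tested genes. Chance gives 33.3% for exchangeable libraries, and the simulation with replicate-number differences and no changed gene gave 14.5%. These shares are for unselected genes. The 90 were selected by a test on the same 4 libraries, so their agreement largely follows from that selection and is no independent support. DESeq2 called 67 genes without control replicate 1, 62 without control replicate 2, 46 without TGF-β1 replicate 1 and 71 without TGF-β1 replicate 2, and 33 of the 90 were called in each of these fits. On simulated counts with no changed gene, DESeq2 called 29 genes when libraries varied independently and 1 when replicate numbers kept their measured differences.

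**Figure D1:**
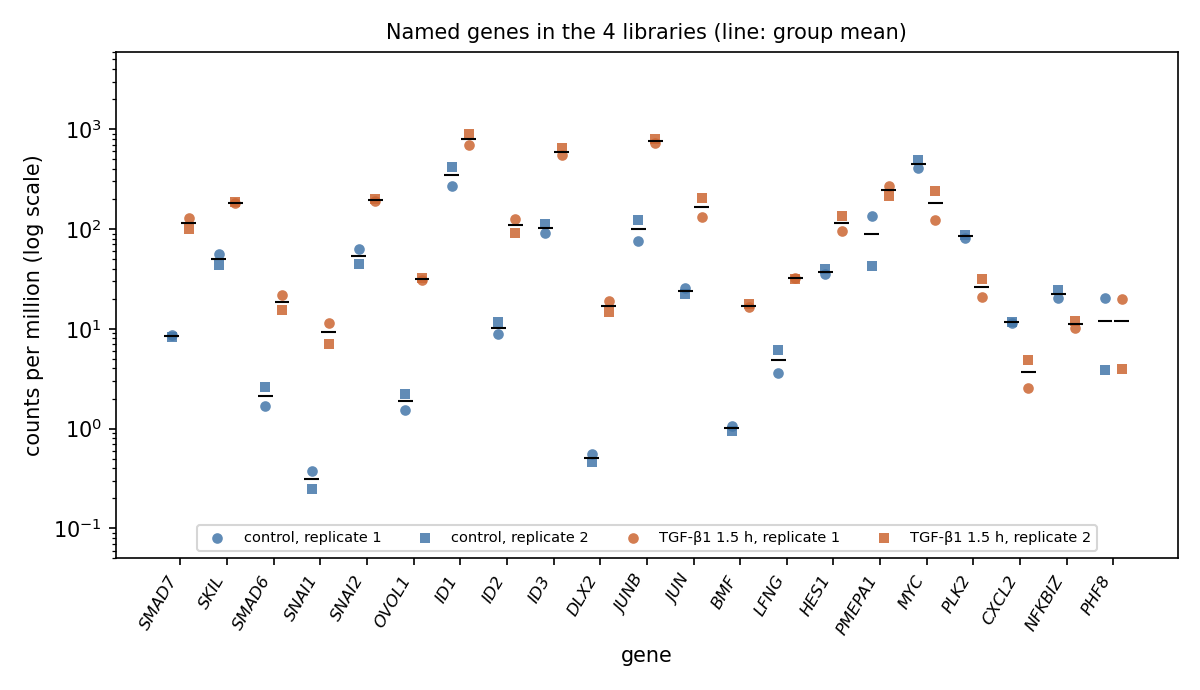
CPM (log axis) of named genes in the 4 libraries, with circles for replicate 1, squares for replicate 2, blue for control, orange for TGF-β1 at 1.5 h, and a black line at each group mean. SMAD7 moved from 8.43 to 114 CPM, while PHF8 was near 20 CPM in both libraries numbered 1 and near 4 CPM in both numbered 2.

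Among the 14 measured feedback regulators of TGF-β signalling, 4 rose by DESeq2 and 0 fell. These were SMAD7 on chromosome 18 (48919853 to 48952052), SKIL, SMAD6 and the pseudoreceptor BAMBI. SKIL, a SMAD co-repressor, rose 3.67-fold from 50.1 ± 8.96 to 184 ± 4.26 CPM (DESeq2 adjusted p = 4.86e-12, edgeR adjusted p = 0.217). SMAD6, an inhibitory SMAD, rose 8.70-fold from 2.14 ± 0.642 to 18.6 ± 4.6 CPM. The log2 fold change of SMAD7 was 3.76 ± 0.18 (SE) by edgeR and its DESeq2 adjusted p was 6.27e-47. PMEPA1, a membrane protein that sequesters SMADs, had 88.8 ± 64.9 CPM in the controls and 244 ± 39.2 CPM after TGF-β1. It passed neither test without a block (DESeq2 adjusted p = 0.533, edgeR adjusted p = 1.00). Its log2 fold changes were 1.01 within replicates 1 and 2.33 within replicates 2. Its controls had 135 and 43.0 CPM in replicates 1 and 2. DESeq2 called it higher without control replicate 1, where only the lower control remained. DESeq2 did not call BAMBI without any 1 of the 4 libraries. Adjusted over the list alone, edgeR called 6 members, SMAD7, SKIL, SMAD6, BAMBI, SKI and TGIF1. Camera placed the list above the other genes (adjusted p = 1.80e-15), with adjusted p = 0.217 with an estimated correlation. That estimate was 0.0127, near the preset 0.01, so correlated genes do not explain the higher p.

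Of 27 early TGF-β targets known from other epithelial cells, 9 rose by DESeq2 and 0 fell. BHLHE40, a helix-loop-helix repressor, rose 5.22-fold from 60.6 ± 0.649 to 316 ± 49.3 CPM (DESeq2 adjusted p = 6.87e-23, edgeR adjusted p = 0.159). GADD45B, a stress-response protein, rose 6.41-fold, and CCN2, a matricellular protein, rose 3.56-fold. Leaving out a library gave 10 higher members without control replicate 1, 6 without control replicate 2, 5 without TGF-β1 replicate 1 and 8 without TGF-β1 replicate 2. The CCN2 call ended without control replicate 2 (DESeq2 adjusted p = 0.0721) and without TGF-β1 replicate 1 (0.188). Adjusted over the list alone, edgeR called 9 members, all higher. Camera gave the list an adjusted p of 5.32e-18, and adjusted p = 0.483 with an estimated correlation. Of the 21 TGF-β ligands, receptors and SMADs, DESeq2 called 0 and edgeR 0, also when adjusted over the list alone (0 at an unadjusted p under 0.05), with a camera adjusted p of 0.658. Their median log2 fold change was -0.01 and their mean 0.003.

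The ID family and other genes known to respond to BMP had the highest median log2 fold change of the 29 lists, 1.64, and 7 of 11 measured members rose by DESeq2, with 0 lower. ID2 and ID3, which block helix-loop-helix transcription factors, rose 10.6-fold (10.2 ± 1.94 to 109 ± 25.6 CPM) and 5.86-fold (102 ± 14.4 to 596 ± 66.3 CPM). ID1 rose 2.29-fold from 345 ± 108 to 790.2 ± 134 CPM (DESeq2 adjusted p = 0.0193). That call ended without control replicate 1 (0.549), TGF-β1 replicate 1 (0.0566) or TGF-β1 replicate 2 (0.631). DLX2, a homeobox factor, rose 32.8-fold from 0.509 ± 0.0634 to 16.8 ± 3.07 CPM. GATA2, HEY1 and ATOH8 were the other members that rose. The count of 7 became 4 without control replicate 1 or TGF-β1 replicate 1, 6 without control replicate 2 and 5 without TGF-β1 replicate 2, and DLX2, HEY1, ID2 and ID3 were called in each of these fits. Adjusted over the list alone, edgeR called these 7 genes. Camera gave the list an adjusted p of 7.06e-26, and adjusted p = 0.217 with an estimated correlation.

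Among 14 Notch pathway genes, 3 rose by DESeq2 and 0 fell. LFNG, which glycosylates Notch receptors, rose 6.51-fold from 4.91 ± 1.82 to 31.9 ± 0.755 CPM. The Notch target genes HES1 and HEY1 rose 3.07-fold and 8.82-fold. The edgeR log2 fold change of HEY1, 3.141 with all libraries, was 2.498 without TGF-β1 replicate 1. The other 11 did not pass. HES1 is also on the list of early TGF-β targets and HEY1 on the ID list, so of the 3 only LFNG is particular to this list. Adjusted over the list alone, edgeR called these 3 genes, and camera gave the list an adjusted p of 1.63e-07, with adjusted p = 0.483 with an estimated correlation. The camera calls of this list, the ID list, the early targets and the feedback regulators were the 4 of 14 list calls that held without each library in turn.

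**Figure D2:**
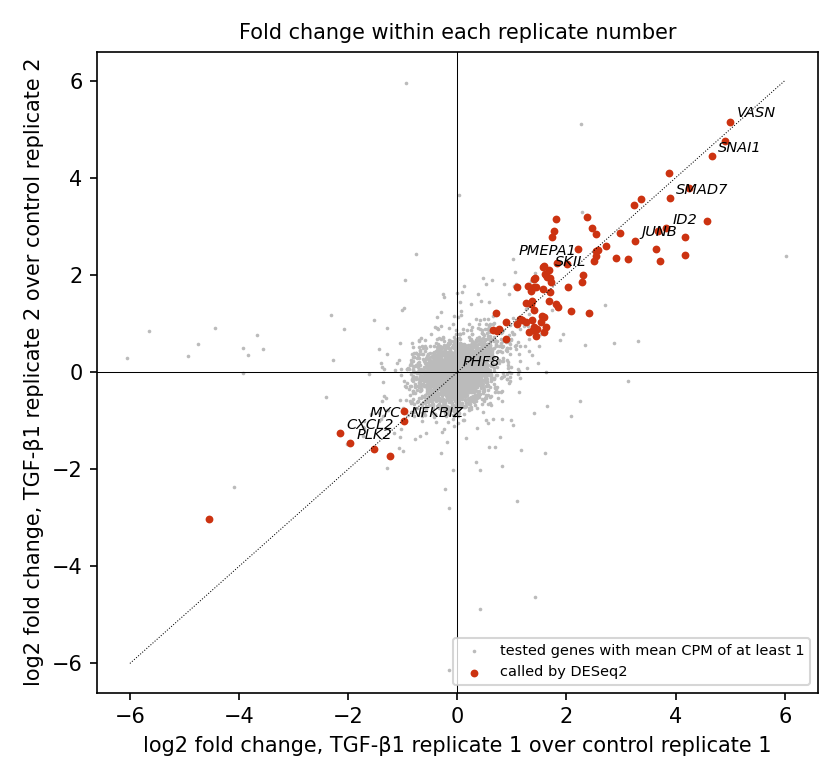
Log2 fold change of TGF-β1 replicate 1 over control replicate 1 (horizontal) against that of TGF-β1 replicate 2 over control replicate 2 (vertical) for tested genes with a mean of at least 1 CPM, in grey, with the genes called by DESeq2 in red and equality as a dotted line. The 83 higher calls lie in the upper right and the 7 lower calls in the lower left.

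Of 15 EMT transcription factors, 2 rose by DESeq2 and 0 fell. SNAI1 on chromosome 20 (49982999 to 49988886) had a DESeq2 adjusted p of 5.89e-18 and an edgeR adjusted p of 0.217. SNAI2, the related repressor also called SLUG, rose 3.63-fold from 53.8 ± 13.4 to 195 ± 8.72 CPM. The forkhead factor FOXC1 had a log2 fold change of 0.47 ± 0.13 (SE) and did not pass without a block. Its values were 0.48 within replicates 1 and 0.46 within replicates 2. Of 24 epithelial junction and identity genes, 1 rose and 0 fell. This was OVOL1, a zinc-finger factor known to restrain EMT, which rose 16.6-fold from 1.89 ± 0.497 to 31.3 ± 0.898 CPM. Its relative OVOL2 had a log2 fold change of 0.81 ± 0.19 (SE), with 0.81 within replicates 1 and 0.79 within replicates 2. The tight-junction gene CLDN4 had one of 0.57 ± 0.31 (SE), with 0.64 and 0.46, and its groups overlapped. Neither gene passed without a block. Adjusted over each list alone, edgeR called SNAI1 and SNAI2 in the first and OVOL1 in the second. Camera gave adjusted p = 0.00133 and 0.0247 for these lists, and adjusted p = 0.497 and 0.566 with an estimated correlation. The camera call of the EMT factors ended without control replicate 2 (0.212) and without TGF-β1 replicate 1 (0.132). That of the epithelial genes ended without control replicate 1 (0.062), control replicate 2 (0.23) or TGF-β1 replicate 1 (0.553).

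No mesenchymal or matrix gene was called among the 25 measured (0 by DESeq2, 0 by edgeR over all genes or over the list alone, 0 at an unadjusted edgeR p under 0.05). The camera adjusted p of that list was 0.633, with an upward direction although its median and mean log2 fold changes were -0.09 and -0.05. It passed upward without control replicate 1 (5.01e-05) and downward without control replicate 2 (0.000473). Of the 14 basal mammary markers, all had a positive log2 fold change, with a median of 0.10, and 0 were called by DESeq2 or edgeR (1 at an unadjusted edgeR p under 0.05). Camera gave them an adjusted p of 0.0118, and adjusted p = 0.483 with an estimated correlation. That call ended without control replicate 2 (0.54), TGF-β1 replicate 1 (0.305) or TGF-β1 replicate 2 (0.0872). The 7 measured luminal markers, 5 fibroblast markers and 6 markers of blood and endothelial cells held 0 genes called by DESeq2 or edgeR and 0 at an unadjusted edgeR p under 0.05. Their camera adjusted p were 0.732, 0.756 and 0.186, and the median and mean of the fibroblast markers had opposite signs (-0.05 and 0.09). The blood and endothelial list passed downward without control replicate 1 (0.0396).

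Of 23 immediate-early genes, which are transcribed soon after a stimulus, 5 rose by DESeq2 and 0 fell. By edgeR, 7 were higher and 4 lower at an unadjusted p under 0.05, so members moved both ways. The AP-1 subunits JUN and FOSB rose 7.05-fold (23.8 ± 2.23 to 168 ± 49.9 CPM) and 7.14-fold (0.623 ± 0.186 to 4.48 ± 0.104 CPM). KLF4, FOS and MAFF also rose. DESeq2's MAFF call ended without any 1 library, and its FOS call ended without control replicate 1 or TGF-β1 replicate 2. Adjusted over the list alone, edgeR called 7 members, of which 6 were higher and DUSP6, a phosphatase of ERK, was lower. Camera gave the list an adjusted p of 0.00133, and adjusted p = 0.483 with an estimated correlation. The camera call ended without control replicate 1 (0.17) and without TGF-β1 replicate 2 (0.062). DESeq2's count of 5 became 3 without either control and 2 without either TGF-β1 library, with JUN called in each, and DUSP6 was called lower without control replicate 2. The FOSB call ended without TGF-β1 replicate 1 (0.214), and the KLF4 call ended without control replicate 2 (0.252), TGF-β1 replicate 1 (0.605) or TGF-β1 replicate 2 (0.0917).

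In the cytostatic program, 2 of 15 genes rose by DESeq2, GADD45B and its relative GADD45A (2.06-fold), and 0 fell. MYC, the growth-promoting transcription factor, was at 446 ± 59.9 CPM in the controls and 182 ± 83.9 CPM after TGF-β1 and passed neither test without a block (DESeq2 adjusted p = 0.0853, edgeR adjusted p = 1.00). Its log2 fold changes were -1.72 within replicates 1 and -1.02 within replicates 2, and DESeq2 called it lower without TGF-β1 replicate 2. The cyclin-dependent kinase inhibitor CDKN1A had a log2 fold change of 0.67 ± 0.14 (SE; 0.68 within replicates 1 and 0.66 within replicates 2), a DESeq2 adjusted p of 0.277, and was called by edgeR when adjusted over the list alone, with GADD45A and GADD45B. Camera gave the list an adjusted p of 0.00897, and adjusted p = 0.483 with an estimated correlation. Of 17 p53 targets, 1 fell (PLK2) and 0 rose by DESeq2, while edgeR, adjusted over the list alone, called PLK2 lower and CDKN1A and the kinase PLK3 higher (camera adjusted p = 0.805). Of 24 proliferation genes, 0 were called by DESeq2 or edgeR and 0 had an unadjusted edgeR p under 0.05 (camera adjusted p = 0.732). That list passed downward without control replicate 2 (5.92e-06) or TGF-β1 replicate 1 (1.05e-05), and upward without control replicate 1 (0.000345) or TGF-β1 replicate 2 (0.000721). DESeq2's GADD45A call ended without any 1 of the 4 libraries (adjusted p 0.145 to 1.00), and the cytostatic camera call ended without control replicate 2 (0.324) and without TGF-β1 replicate 1 (0.586).

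Of 30 cytokines and growth factors, 3 rose by DESeq2 and 1 fell (6 higher and 3 lower at an unadjusted edgeR p under 0.05). VEGFA, the vascular endothelial growth factor, rose 3.41-fold from 45.5 ± 14.4 to 155 ± 25.2 CPM, the WNT ligand WNT9A rose 5.80-fold, and PDGFA also rose. CXCL2, a chemokine for neutrophils, fell 3.14-fold from 11.6 ± 0.206 to 3.71 ± 1.67 CPM. Of 15 NF-κB feedback and inflammation genes, 1 rose by DESeq2, TNFAIP2 (1.71-fold), and 0 fell. By edgeR, 3 were higher and 2 lower at an unadjusted p under 0.05. CEBPD and BIRC3 in that list had log2 fold changes of -1.40 ± 0.43 and -0.83 ± 0.19 (SE) and passed neither test without a block. Within replicates 1 and 2 the values were -0.995 and -1.63 for CEBPD, and -0.84 and -0.83 for BIRC3. Among 16 genes that respond to YAP and TEAD, GADD45B and CCN2 rose, both also on the list of early TGF-β targets. CCN1 had a log2 fold change of 1.35 ± 0.41 (SE; 1.07 within replicates 1 and 1.80 within replicates 2) and did not pass without a block. Adjusted over each list alone, edgeR called 0 cytokines, TNFAIP2 in the NF-κB list, and GADD45B and CCN2 in the YAP list. Camera gave adjusted p of 0.732, 0.633 and 0.000675 for the 3 lists, the last with adjusted p = 0.497 with an estimated correlation. The median and mean of the NF-κB list differed in sign (0.12 and -0.03). DESeq2 called 2 cytokine genes higher and 0 lower without control replicate 1, 2 higher and 2 lower (CXCL1 and CXCL8) without control replicate 2, 1 higher and 0 lower without TGF-β1 replicate 1, and 5 higher and 1 lower without TGF-β1 replicate 2. The PDGFA call held in the last of these fits alone, and VEGFA was called in all 4. The edgeR log2 fold change of WNT9A, 2.536 with all libraries, was 3.18 without control replicate 1 and 1.872 without TGF-β1 replicate 1. Without control replicate 1, CEBPD was called lower and CCN1 higher. The cytokine list passed camera without control replicate 1 (0.0293). The YAP camera call ended without control replicate 2 (0.217) and TGF-β1 replicate 1 (0.132), DESeq2's WNT9A call without TGF-β1 replicate 1 (0.105), its CXCL2 call without control replicate 1 (0.474), control replicate 2 (0.611) or TGF-β1 replicate 1 (1.00), and its TNFAIP2 call without any 1 library (0.942 to 1.00).

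Of 17 hypoxia and glycolysis genes, 1 rose by DESeq2 and 0 fell. PFKFB3, which makes an activator of glycolysis, rose 3.21-fold from 34.0 ± 3.51 to 109 ± 14.05 CPM. NDRG1 and ADM had log2 fold changes of 0.65 ± 0.13 and 0.78 ± 0.35 (SE) and did not pass over all genes without a block. Within replicates 1 and 2 the values were 0.62 and 0.67 for NDRG1, and 0.63 and 0.86 for ADM. EdgeR called PFKFB3 and NDRG1 when adjusted over the list alone. All 16 cholesterol synthesis genes had a negative log2 fold change, with a median of -0.19, and 0 were called by DESeq2 or edgeR. Of the 13 mitochondrially encoded mRNAs, 11 had a negative log2 fold change and 0 were called. Of 18 histone lysine demethylases, 14 had a positive log2 fold change and 0 were called (2 higher at an unadjusted edgeR p under 0.05). PHF8 had a log2 fold change of -0.005 ± 1.08 (SE). Camera gave these 4 lists adjusted p of 0.00148, 0.036, 0.0458 and 0.00939, and with an estimated correlation adjusted p = 0.558, 0.892, 0.892 and 0.483. The cholesterol list turned upward without control replicate 1 (0.0393) or TGF-β1 replicate 2 (0.694), the mitochondrial list turned upward without TGF-β1 replicate 1 (0.607) and was not past the threshold without control replicate 2 (0.95). The hypoxia call ended without control replicate 2 (0.351) and TGF-β1 replicate 1 (0.42), and the demethylase call without any 1 library (0.0552 to 0.278).

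DESeq2 and edgeR called 0 genes in the WNT pathway (16 measured), heat shock (15), ATF4 and unfolded-protein response (18), interferon-stimulated (21) and reference gene (15) lists, and edgeR had 1 gene at an unadjusted p under 0.05 in the heat shock list and 0 in the others. Their camera adjusted p were 0.805, 0.428, 0.658, 0.211 and 0.732. The reference genes had log2 fold changes between -0.12 and 0.19, with a median of 0.02. The interferon list passed without TGF-β1 replicate 2 (0.0136) and with the stricter filter (0.012). Transcript lengths as an offset ended the camera calls of the epithelial, cytostatic, demethylase and mitochondrial lists (adjusted p 0.324, 0.0511, 0.0587 and 0.241). Without a filter the epithelial, basal, cholesterol and mitochondrial lists did not pass (0.0517, 0.0517, 0.0955 and 0.18).

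**Figure D3:**
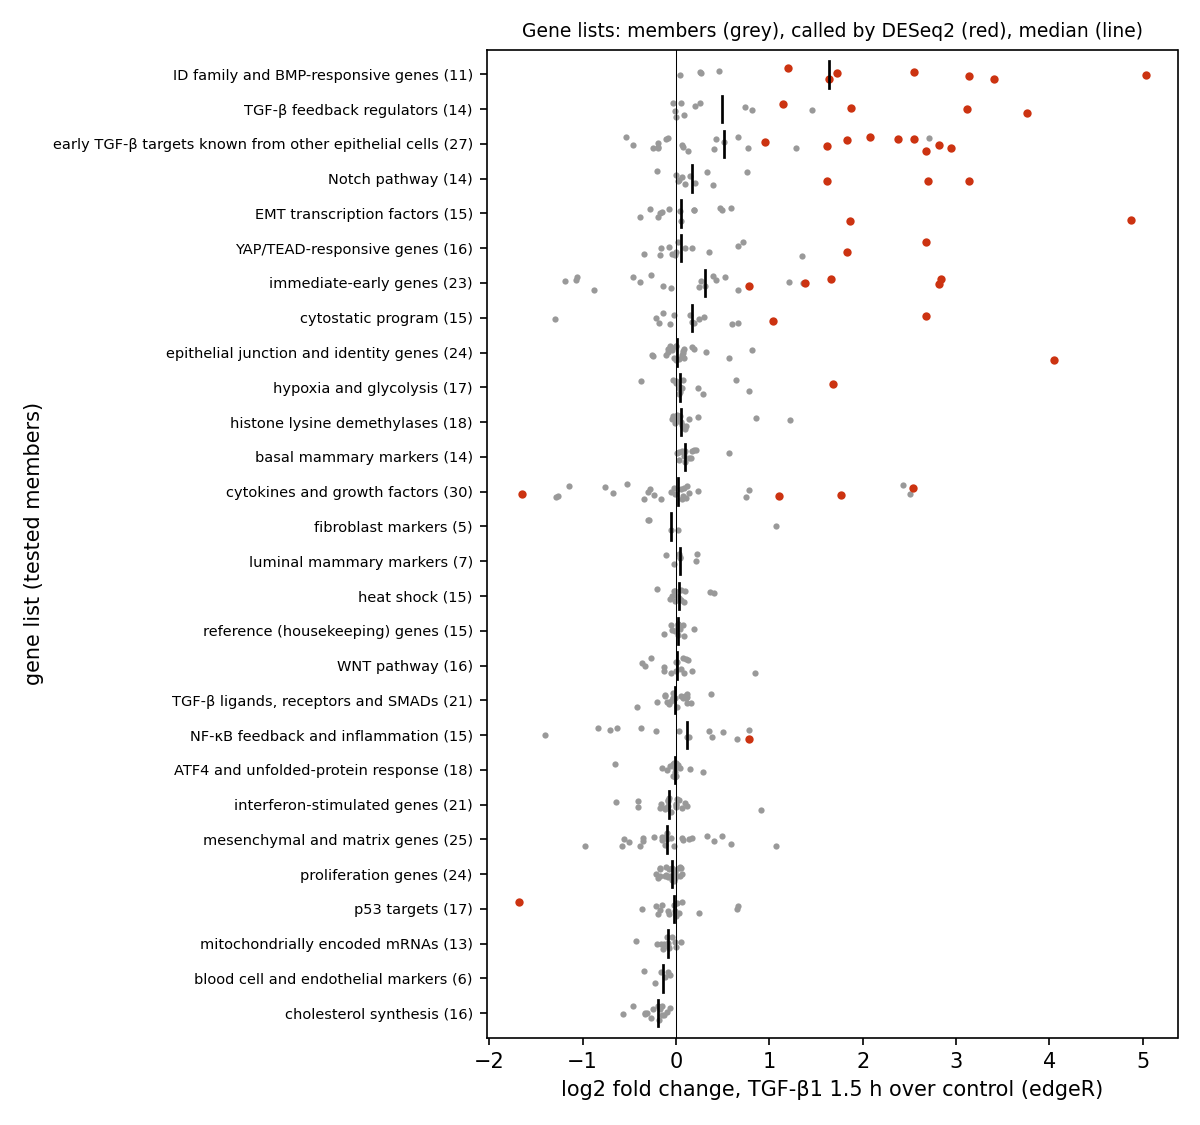
Log2 fold change by edgeR (horizontal) of the tested members of the gene lists reported here (vertical, number of tested members in brackets, ordered by mean), with members called by DESeq2 in red, the others in grey and the list median as a black line. The ID list has a median of 1.64 with 7 of 11 members in red, and the reference genes a median of 0.02.

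Outside the lists, the genes with the largest log2 fold changes by the naming rule were VASN, BMF, EDN2, SAMD11 and CSRNP1. VASN, a membrane protein that binds TGF-β, rose 34.9-fold from 1.45 ± 0.658 to 50.9 ± 18.4 CPM. Its only transcript with reads had the same estimated counts in each library as a transcript outside the gene table, so its reads were split between copies and its level is uncertain. BMF rose 16.9-fold from 1.01 ± 0.0718 to 17.1 ± 0.721 CPM, and CSRNP1 rose 10.2-fold from 8.26 ± 1.03 to 84.1 ± 2.08 CPM (DESeq2 adjusted p = 3.96e-43). EDN2, which encodes endothelin-2, rose 12.9-fold and SAMD11 rose 12.4-fold. Besides PLK2 and CXCL2, the lower genes were CITED2, a CBP/p300-binding transcriptional regulator (2.99-fold), H4C15, a histone H4 gene (2.94-fold), NFKBIZ, a nuclear IκB protein (2.0-fold), and NCOA7 (1.84-fold). The last of the 7, NDUFC2-KCTD14, a read-through of neighbouring genes, is named after its values were seen, with 71 and 21 counts in the controls and 0 in both treated libraries. Its reads are shared with those genes, so the call is uncertain. The DESeq2 calls of H4C15, NFKBIZ and NCOA7 ended without any 1 of the 4 libraries (adjusted p 0.136 to 1.00, 0.696 to 1.00 and 0.331 to 1.00), that of CITED2 without control replicate 2 or TGF-β1 replicate 1 (1.00), and that of EDN2 without TGF-β1 replicate 2 (0.0622). By edgeR, the log2 fold change of EDN2 was 3.694 with all libraries, 5.532 without control replicate 2 and 2.901 without control replicate 1.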

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

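Among transcripts that match no gene of the annotation, and so stand outside the gene-level comparison, 6 were higher after TGF-β1 by DESeq2 on single transcripts and 8 were lower, of 5866 with counts. Over all transcripts, 407 of 116568 were called, a larger share. Of the 6 higher, 2 (ENST00000416639 and ENST00000443235) had the same counts in each library, 0 and 0 in the controls and 116 and 140 after TGF-β1, so they may be a single signal. The level in the control libraries was the reference, and the test was made only after the data were seen. The transcript ENST00000622615 rose from 76 and 36 estimated counts in the controls to 2499 and 1306 after TGF-β1, the same values as the VASN transcript. ENST00000458592 fell from 456 and 280 to 12 and 2. The files do not pair these identifiers with gene names, and no explanation was tested.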

How the results depend on the processing

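Counts of genes past the threshold depended on the test and on the replicate numbers. Against 0 genes by edgeR's quasi-likelihood test, edgeR gave 15 without a filter (15 higher, 0 lower, 15 at least 2-fold) and 3 with transcript lengths as an offset (3 higher, 3 at least 2-fold). DESeq2 gave 90 (83 higher, 7 lower, 82 at least 2-fold). EdgeR gave 0 with RLE scaling, the stricter filter, the 0.01 threshold, single transcripts and, added after the data were seen, the robust and version 4 fits, and limma on TPM gave 0. DESeq2 on single transcripts, also added then, called 407 of 116568. Leaving out 1 library, edgeR gave 8 to 25 genes (8 to 20 higher, 0 to 5 lower, 8 to 25 at least 2-fold), where the lone library is assumed to vary like the other group. DESeq2 then gave 46 to 71 (40 to 62 higher, 5 to 17 lower, 46 to 71 at least 2-fold), with 0 changes of sign among its 90 genes. The replicate numbers were not used as pairing, since there are only 2 pairs and the labels do not say what a number marks. With the replicate block edgeR gave 335 genes (259 higher, 76 lower, 124 at least 2-fold) and DESeq2 245 (194 higher, 51 lower, 104 at least 2-fold). In simulated libraries with the measured replicate-number differences, 30 of 230 calls of the blocked edgeR fit were of unchanged genes. All 90 DESeq2 genes were among the 335 and 86 among the 245. Same-numbered libraries deviated together with a correlation of 0.678 across genes, and of 0.829 across the 9380 genes with a mean of at least 10 CPM. Camera's 14 list calls became 7 to 16 without 1 library, and 0 with an estimated correlation or with fry. They became 10 without a filter or with the length offset, and 13 with the block, which ended the call of the epithelial list (camera adjusted p = 0.203). The loss with an estimated correlation need not come from correlated genes. For the demethylases the estimate was -0.0586, below the preset 0.01, yet the unadjusted camera p went from 0.00324 to 0.086. Other called lists had larger estimates, up to 0.928 for the mitochondrial mRNAs. Some lists turned: mesenchymal downward without control replicate 2 (adjusted p over the left-out libraries from 5.01e-05 to 0.4905), proliferation and cholesterol upward without control replicate 1 or TGF-β1 replicate 2 (5.92e-06 to 0.0007211 and 4.92e-08 to 0.6935), and mitochondrial upward without TGF-β1 replicate 1 (0.00364 to 0.9504). Leaving out 1 library leaves the replicate numbers unbalanced between the groups, so the difference between numbers enters the comparison. Each list turned the way that difference would move it. The median log2 difference, number 2 minus number 1, was -0.783 for the mesenchymal and -0.801 for the proliferation list. It was -0.62 for the cholesterol and 0.276 for the mitochondrial list. The EMT, cytostatic, YAP and hypoxia medians were -0.101, -0.33, -0.301 and -0.143. Their calls ended in the fits that such a difference lowers, those without control replicate 2 or TGF-β1 replicate 1. The immediate-early call (median 0.188) ended in the opposite fits, which lower that list. The epithelial, basal and demethylase calls ended in fits of both kinds, so the difference alone does not account for these. The cause of the remaining changes was not tested. Of the 50 named genes, 36 passed the threshold with DESeq2 and 49, PHF8 being the exception, with the replicate block in edgeR. Among those that passed with the block and in neither test without it were MYC (adjusted p = 0.00455), PMEPA1 (0.0275), CDKN1A (0.000633), BIRC3 (0.000227) and CEBPD (0.00346). Totals differ by little between libraries, and depth was tested as a cause of the replicate-number difference only.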

Other observations

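The difference between replicate numbers was the larger axis of these data. In an edgeR fit with treatment as a term, 6635 of 14774 genes differed between the libraries numbered 2 and those numbered 1. Of these, 3700 were lower and 2935 higher in number 2, and 957 differed at least 2-fold. The fit has the same terms as the one with the replicate block, which also called unchanged genes in simulation. If a number marks a batch, its libraries are not independent replicates of it, and the p-values given here measure agreement within a batch only. All 24 proliferation genes were lower in number 2 (median log2 difference -0.80, camera adjusted p = 3.70e-10, adjusted p = 0.79 with an estimated correlation), as were 14 of 16 cholesterol synthesis genes (median -0.62, camera adjusted p = 0.000434, adjusted p = 0.79 with an estimated correlation). Of 25 mesenchymal and matrix genes, 15 were lower and 3 higher (camera adjusted p = 0.00185, adjusted p = 0.79 with an estimated correlation). Named after their values were seen, the matrix genes TNC and FN1 were 6.51-fold and 2.62-fold lower in number 2, and the epithelial splicing regulator ESRP1 was 3.74-fold higher, while the epithelial cadherin CDH1 was 1.31-fold lower (adjusted p = 0.00071). Of 24 epithelial junction and identity genes, 5 were higher and 7 lower (median log2 difference -0.08, camera adjusted p = 0.491). The early TGF-β targets, 18 of 27 lower and 4 higher, and the mitochondrially encoded mRNAs, 8 of 13 higher and 0 lower, also passed (both camera adjusted p = 0.00293, adjusted p = 0.79 with an estimated correlation). So did the cytokines (17 of 30 lower, 5 higher) and the heat shock genes (8 of 15 lower, 0 higher), with camera adjusted p = 0.0261 for both and adjusted p = 0.79 with an estimated correlation. ZEB1 and VIM did not pass (adjusted p = 0.142 and 0.19).

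Of the tests that follow, those on PHF8, on the scaling of the libraries, on the 2 gene properties as applied to DESeq2's genes, and the contrast of replicate numbers were chosen only after results had been seen. The first principal component held 65.9% of the variance and separated the numbers, and the second held 21.7% and separated the treatment. Depth does not account for this, since the correlation of same-number deviations was 0.678 before and 0.675 after all libraries were thinned to the smallest total. GC content and transcript length do not either, with 0.677 after both trends were removed. A difference in library or culture batch stays open, since the labels give none. The labels' protocol mentions overexpression of PHF8, so the level near 20 CPM in number 1 could be the altered one as well as that near 4 CPM in number 2. Altered PHF8 in either pair, or a mislabelled pair, cannot be told apart from such a batch difference, since both libraries of a number share it and the rank of PHF8 restates the levels that prompted the question. PHF8 ranked 82 of 14774 genes by the size of its difference, 5.10-fold lower in number 2 (adjusted p = 2.89e-05), while the 17 other demethylases lay between -0.41 and 0.36 on the log2 scale. Other genes differed more, and no library was regrouped.

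More genes were higher than lower after TGF-β1 (83 against 7 by DESeq2). With the replicate block the counts were 194 against 51 by DESeq2 and 259 against 76 by edgeR, which is less one-sided. The excess was smaller without TGF-β1 replicate 2 (54 against 17) and without TGF-β1 replicate 1 (40 against 6), and it was 62 against 5 and 56 against 6 without control replicates 1 and 2. A scaling error could give such an excess. The 15 reference genes, however, had a median log2 fold change of 0.02, against a median size of 1.76 for the called genes. With size factors from them DESeq2 again gave 83 higher and 7 lower, which largely follows from that median and is no separate check. A change in total mRNA that the reference genes share would not be seen this way. Early induction by TGF-β1 stays open as a hypothesis, as does the lower power for mRNAs that decay slowly, which was not tested.

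Since edgeR called no gene, 2 hypotheses written before their results were seen were tested on DESeq2's genes. The first was that genes higher after 1.5 h are short enough to be transcribed in that time. The 82 higher protein-coding genes had a median genomic span of 12626 bp, against 34218 bp for 10000 random lists matched on expression (central 95% from 24526 to 48291 bp), a percentile of 0.01, the smallest the lists can give. The second was that genes that changed carry 3' UTR signals of short-lived mRNA. An AU-rich nonamer was present in 29.5% of the 88 called genes with an annotated 3' UTR, against a median of 17% in lists matched on expression and 3' UTR length (central 95% from 10.2% to 26.1%). Both results may reflect the known make-up of early-response genes, and neither shows that span or motif sets the response. The first shows only that the higher genes were shorter than matched genes. No transcription speed was measured, so whether longer genes lacked the time cannot be told.

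Some genes were on in 1 group and off in the other, with at least 15 counts in both libraries of a group and at most 1 in each of the other. Between control and TGF-β1 there were 4, namely NDUFC2-KCTD14, LRRC37A and AL121758.1 off after TGF-β1 and AC090527.2 off in the controls, named after their values were seen. The split by replicate number gave 10 and the remaining split of the 4 libraries 3.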
